A study of Mus musculus with 8 samples.

How the data were processed

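RNA from 8 mammary glands of 4 Balb/cJ mice was measured on Affymetrix mouse 430A arrays, which report the level of each transcript by a set of short probes. Per the labels' protocols, excised glands were kept in RNAlater and total RNA was isolated with a lipid tissue kit and labelled with biotin. The deposited table holds 1 log2 value per probe set and array. Per the submitters' processing notes, these values were made with RMA, which corrects the background, applies quantile normalization and summarises the probes of a set. The version and the software, and whether all arrays were processed in 1 run, are not given in the sources used here. The log2 scale of the deposited values was read from their range, 3.54 to 14.7. RMA compresses small changes at the bottom and the top of that range, so changes of very dim or very bright genes may be understated. Probe set values have no read depth, and the number of arrays limits the precision.

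Of 22690 probe sets, 64 were controls, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 others had none. Symbols were checked through Entrez identifiers against a RefSeq gene table, which held 20351 of them and changed 0. Each gene was represented by its probe set with the highest mean over the 8 arrays, which gave 12393 genes, 4956 of them with over 1 probe set. Probe sets with several symbols or none were left out of the gene tests. No filter on dim probe sets was applied.

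The 4 groups were set from the sample titles, as saline or E. coli at 24 h or 48 h, with 2 arrays each. The series describes a split plot in which each mouse gave both glands. The labels name no mouse, so glands of the same time and replicate number were assumed to come from 1 mouse. All values within mice rest on this assumption. Deviations from the group means correlated within pairs at 0.637 for 24 h and 0.430 for 48 h. Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and the mouse as a random block through duplicateCorrelation (statmod 1.5.0), whose consensus correlation was 0.464. The average E. coli effect was fitted with treatment and time, with a correlation of 0.367. Tests were two-sided, moderated with eBayes, and called at a Benjamini-Hochberg adjusted p under 0.05. Every p given for a gene or a list comes from these models. In fits without both glands of a mouse the correlation could not be estimated, and 0.464 was used.

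Gene lists were tested with the camera test of limma on the moderated statistics, with a preset correlation of 0.01, and adjusted over the 42 lists. The lists, the groups, the models, the alternatives tried and the rule for named genes were fixed before the data were examined. Genes in a list were counted as called over all genes and adjusted over the list alone. Alternatives for the lists were an estimated correlation, fry, ranks and no block.

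Named genes followed a rule. For E. coli against saline at each time they were the 8 largest rises and 8 largest falls among called genes that changed the same way in both mice. From each list they were up to 3 called genes, or otherwise up to 2 with the highest mean, and 16 genes were always included. For the difference of effects and for time they were the 6 largest rises and 6 largest falls among called genes, or the called ones plus those with the smallest p up to 3. Other genes are named as chosen after their values were seen.

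Alternatives for the gene tests were no mouse block, the mouse as a fixed block, a further quantile normalization, median centring, leaving out the lowest 33% of genes, all probe sets, eBayes with trend and robust settings, array weights, only the arrays compared, a minimum of 2-fold, an adjusted p under 0.01, and leaving out each array. Leaving out both glands of each mouse was chosen after seeing the data. A lone array in a group was assumed to vary like the other groups. Leaving out an array of a group outside a comparison kept the values compared, so passing in such a fit did not test the arrays compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

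The gene test was tested on simulated data for the 24 h comparison of E. coli with saline, on 12393 genes with 200 changed in each of 10 runs. It recovered 96.8% of genes changed 1.5-fold, 99.0% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, with 5.8% false among the called, and it called 0.5 genes per run when no gene was changed. The spread was drawn from the moderated variances with 1 correlation within mice for all genes, so genes more variable than the model assumes were not covered. With 200 changed genes the adjusted threshold is also easier to reach than with few. Recovery in the measured data can therefore be lower, and S100a8, S100a9 and Saa3, with folds above 3 at 24 h, did not pass there. The list test called the shifted list in 10 of 10 runs, and 1 unshifted list over all runs. Simulated genes were drawn independently, so false calls for lists whose genes vary together were not covered.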

Results

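Gene expression was measured in mammary glands of 4 lactating Balb/cJ mice after an injection of Escherichia coli, a common bacterial agent of mastitis, which is inflammation of the mammary gland. The females were in their first lactation, between day 5 and day 8 after delivery. In each mouse the fourth left gland received saline and the fourth right gland received E. coli. Glands were taken 24 h after injection from 2 mice and 48 h after injection from the other 2, which gave 8 arrays in 4 groups of 2. The replicates were separate mice, and each mouse gave a saline and an E. coli gland. Treatment was thus tied to body side, time was tied to the mouse and to any processing day, and no uninjected gland was measured. Values were on a log2 scale, with 1 probe set per gene, and 12393 named genes were tested. Median values per array lay between 7.53 and 7.58, and the number of arrays limited the precision. The ratio of 3-prime to 5-prime signal for Actb, a sign of RNA integrity that rises as RNA degrades, ranged from 1.17 to 1.45 over the 8 arrays. It was lowest in both glands of mouse 2 at 48 h, at 1.22 for saline and 1.17 for E. coli.

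To find which genes responded to the bacteria within the first day, E. coli glands were compared with the saline glands of the same mice at 24 h. Among the genes that rose were 2 chemokines and 2 acute-phase genes. Cxcl2, a chemokine that recruits neutrophils, rose 6.23-fold (95% CI 5.19 to 7.49, adjusted p = 9.46e-06), from a log2 value of 5.79 ± 0.09 to 8.42 ± 0.37 (mean ± SD, n = 2). Ptx3, which encodes a soluble pattern-recognition protein, rose 6.32-fold (95% CI 3.68 to 10.9, adjusted p = 0.0214), and its E. coli glands varied widely, at 7.36 ± 1.32. The log2 change of Ptx3 ranged from 1.73 to 3.59 when 1 array was left out. The saline level of Ptx3, 4.70, lay next to the 5th percentile of the arrays, 4.62 and 4.65 in these glands, and was not shown to be above background, so the size of the fold is uncertain. Cxcl1, another neutrophil attractant, rose 3.69-fold (95% CI 2.65 to 5.14, adjusted p = 0.0164). Fcgr1, a high-affinity receptor for immunoglobulin G on monocytes and macrophages, rose 3.27-fold (95% CI 2.21 to 4.86, adjusted p = 0.0438).

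Smaller rises at 24 h were found for the acute-phase genes Hp (haptoglobin), at 2.15-fold (adjusted p = 0.0214), and Serpina3n, at 1.77-fold (adjusted p = 0.0214). The cytokine genes Il6 and Il1b rose 1.89-fold (adjusted p = 0.0164) and 1.72-fold (adjusted p = 0.0314). For Il6 the saline level, 4.36, lay below the 5th percentile of these arrays, so the size of its fold is uncertain. Cfb, which encodes complement factor B, rose 1.85-fold (adjusted p = 0.0214), and Icam1, a leukocyte adhesion molecule, rose 1.55-fold (adjusted p = 0.0176). The other 5 genes past the threshold, Pdpn, Plekhs1, Ccr1, Map3k8 and Clec4n, are outside the naming rule and were chosen after their values were seen. They rose by 0.76, 0.69, 0.67, 0.64 and 0.60 on the log2 scale. A second probe set of Ccr1 gave 0.00 and a second one of Clec4n gave 0.27. That of Ccr1 had a mean of 4.21, below the 5th percentile of every array, so it says little about a change. In all, limma called 15 genes at 24 h, 15 higher and 0 lower, of which 5 rose at least 2-fold, and 932 genes had an unadjusted p under 0.05 against 619.7 expected by chance. Of these 932, 48.2% were higher in E. coli glands, against 59.4% after the arrays were centred on their medians.

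Several genes known from mastitis did not pass the test at 24 h. The neutrophil genes S100a8 and S100a9 had folds of 4.17 (95% CI 2.33 to 7.45, adjusted p = 0.106) and 3.67 (95% CI 2.21 to 6.09, adjusted p = 0.0882). Saa3, an acute-phase gene expressed in the mammary gland, had a fold of 4.43 (95% CI 2.46 to 8.00, adjusted p = 0.0951). For Tnf the log2 change was 0.02 (SE 0.08, adjusted p = 0.977). Lcn2, an iron-scavenging defence protein, had a change of 0.00 (SE 0.07) at a mean log2 value of 14.06, close to the top of the array's range, where the highest value of an array was 14.74. The milk protein genes Wap, Lalba and Csn2, with means of 14.71, 14.44 and 14.08, had changes of -0.01, -0.02 and -0.10, and Fasn, which encodes fatty acid synthase, had -0.11. The receptor genes Cd14, Tlr2 and Tlr4, which take part in sensing bacterial products, had changes of 0.17, 0.20 and 0.08.

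The number of genes called at 24 h depended on the mouse block and on single arrays. Fits without a 48 h array kept every 24 h value and changed only the shared spread and the correlation of paired glands. Passing in them is therefore no test of the 24 h arrays, although they count among the 8 fits below. Without the block limma called 1 gene, Cxcl2, and with only the 4 arrays of 24 h and no block it called 0. Leaving out saline replicate 1 or 2 of 24 h gave 6 and 1 calls, leaving out E. coli replicate 1 or 2 of 24 h gave 8 and 2, and leaving out either E. coli array of 48 h gave 80. Cxcl2 passed the threshold in 8 of 8 such fits, Il6 in 6, Ptx3, Cxcl1, Hp, Cfb, Serpina3n and Icam1 in 4, and Fcgr1 and Il1b in 2.

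**Figure D1:**
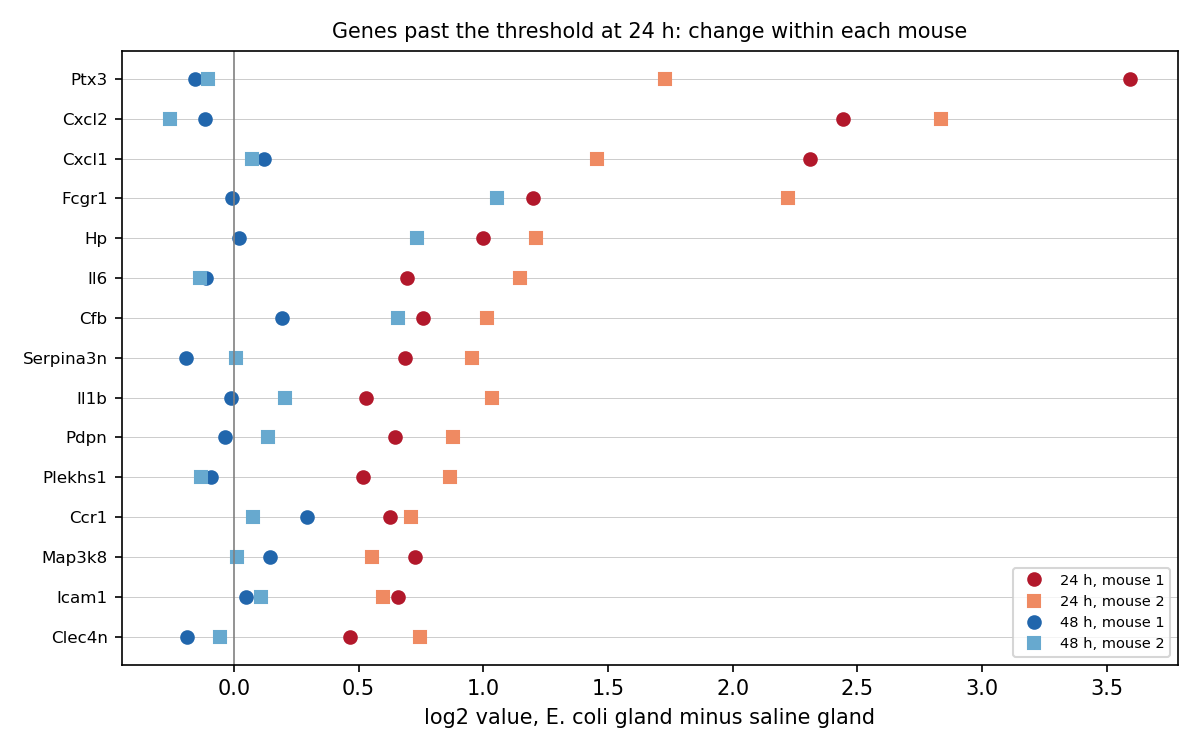
The horizontal axis gives the log2 value of the E. coli gland minus that of the saline gland for the 15 genes called at 24 h, with 1 point per mouse (red and orange for the 24 h mice, dark and light blue for the 48 h mice). For Cxcl2 the changes were 2.44 and 2.84 in the 24 h mice and -0.11 and -0.26 in the 48 h mice.

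Gene lists fixed before the data were examined showed which functions moved together at 24 h. Of 25 measured CXC and CC chemokine genes, 2 rose over all genes tested. Adjusted over the list alone, 16 rose and 3 fell, and the median log2 change was 0.59 (adjusted p = 1.21e-16 in the camera test). The 3 that fell were Ccl22, Ccl17 and Ccl24, at -0.26, -0.20 and -0.19, which are known as attractants of T cells and eosinophils and were chosen after their values were seen. Among 24 genes of the type I interferon response, 0 were called over all genes and 18 rose when adjusted over the list alone. Their median was 0.51 (adjusted p = 4.29e-20 in the camera test, but adjusted p = 0.255 in the rotation test fry). Rtp4 and Ifih1 from that list had changes of 0.97 and 0.37. Among 20 genes of the interferon gamma response and antigen processing, 0 were called over all genes and 13 rose when adjusted over the list alone. Their median was 0.40 (adjusted p = 4.29e-20 in the camera test, but adjusted p = 0.182 by fry). The class I antigen genes H2-K1 and B2m had changes of 0.32 and 0.10. Without both glands of 24 h mouse 2, a fit chosen after seeing the data, the interferon gamma median was 0.23.

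Inflammatory signalling lists were also higher in E. coli glands at 24 h. Of 28 cytokines and receptors, 2 were called, Il6 and Il1b, and 7 rose when adjusted over the list alone (median 0.10, adjusted p = 4.82e-07). Of 17 NF-kB members and feedback targets, 0 were called and 6 rose when adjusted over the list alone (median 0.09, adjusted p = 5.16e-08), and Nfkbia, the NF-kB inhibitor gene, had a change of 0.43 (adjusted p = 0.122). The acute-phase list gave 2 calls and 7 of 20 adjusted over the list alone (median 0.14, adjusted p = 1.43e-07). The list of STAT3 targets and involution genes gave 0 calls and 6 of 25 adjusted over the list alone (median 0.14, adjusted p = 1.17e-07). The list of leukocyte adhesion genes gave 1 call, Icam1, and 3 of 10 adjusted over the list alone (median 0.19, adjusted p = 2.61e-07). The antimicrobial list gave 0 calls and 3 of 18 adjusted over the list alone (median 0.11, adjusted p = 0.000147). Leaving out both glands of 24 h mouse 1 gave medians of 0.35 for leukocyte adhesion and 0.17 for antimicrobial genes, and leaving out those of 24 h mouse 2 gave 0.11 for leukocyte adhesion and 0.15 for NF-kB genes.

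Markers of several cell types differed as lists at 24 h. Of 18 neutrophil markers, 0 were called and 5 rose when adjusted over the list alone (median 0.15, adjusted p = 1.43e-07, and adjusted p = 0.0657 with an estimated correlation). Of 20 monocyte and macrophage markers, 1 was called, Fcgr1, and 5 rose when adjusted over the list alone (median 0.26, adjusted p = 1.08e-09, and adjusted p = 0.139 with an estimated correlation). The 15 complement genes had a median of 0.13, with Cfb as the 1 call and 1 rise adjusted over the list alone (adjusted p = 0.000222, and adjusted p = 0.184 with an estimated correlation). Lists that were lower were skeletal muscle (13 genes, median -0.24, adjusted p = 0.00309, and adjusted p = 0.517 with an estimated correlation) and adipocyte markers (13 genes, median -0.14, adjusted p = 0.0278, and adjusted p = 0.517 with an estimated correlation). In both, 0 members passed the threshold over all genes or adjusted over the list alone. Leaving out both glands of 24 h mouse 1 gave medians of 0.32 for neutrophil markers, 0.22 for complement genes and -0.21 for adipocyte markers, and leaving out those of 24 h mouse 2 gave 0.06 for neutrophil, 0.155 for macrophage and -0.09 for adipocyte markers. The 10 milk protein genes (median -0.05, adjusted p = 0.376) and the 25 milk fat genes (median -0.08, adjusted p = 0.111) were not called.

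The remaining lists higher at 24 h had small medians. Toll-like receptor and lipopolysaccharide sensing (18 genes, median 0.14, adjusted p = 0.00253), the unfolded protein response and heat shock (20 genes, median 0.10, adjusted p = 0.00104), and endothelial markers (13 genes, median 0.07, adjusted p = 0.0238) had 0 members past the threshold, over all genes or adjusted over the list alone. Oxidative stress genes (18 genes, median 0.06, adjusted p = 0.00489) had 0 calls and 3 rises adjusted over the list alone. Coagulation genes (18 genes, median 0.08, adjusted p = 0.00216, and adjusted p = 0.0805 with an estimated correlation) had 0 calls and 3 rises adjusted over the list alone. Fibroblast markers (14 genes, median 0.14, adjusted p = 0.0149, and adjusted p = 0.627 with an estimated correlation) had 0 in both counts. Without both glands of 24 h mouse 1, a fit chosen after seeing the data, the adjusted p was 0.393 for the unfolded protein response and heat shock, 0.393 for endothelial markers, 0.123 for oxidative stress genes, 0.183 for fibroblast markers and 0.123 for skeletal muscle. Without those of 24 h mouse 2 it was 0.363 for adipocyte markers and 0.18 for coagulation genes. The medians were then 0.05 for the unfolded protein response and heat shock, 0.00 for endothelial markers and 0.17 for coagulation genes without mouse 1, and 0.08 for receptor and lipopolysaccharide sensing and 0.03 for coagulation genes without mouse 2. Of 42 lists, 20 were called, 18 higher and 2 lower, and 13 of these were also called with an estimated correlation. The rotation test fry, which asks whether a list's genes move 1 way without comparing them with other genes, called 3 lists, the chemokines, the cytokines and the NF-kB genes. For prolactin and STAT5 genes the median was -0.01 and the mean 0.03, and for luminal epithelial markers the median was 0.01 and the mean -0.01, with neither list called.

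At 48 h the same comparison asked whether the response lasted into the second day. Of the chemokine and cytokine genes called at 24 h, Cxcl2 had a log2 change of -0.19 (SE 0.12, adjusted p = 0.430), Cxcl1 0.10 (SE 0.22, adjusted p = 0.839), Il6 -0.12 (SE 0.10, adjusted p = 0.548, with both groups below the 5th percentile of the arrays) and Il1b 0.10 (SE 0.11, adjusted p = 0.669). Ccl8, a monocyte attractant, did not pass either, with a fold of 1.68 (95% CI 1.09 to 2.59, adjusted p = 0.240). Saa3 had a fold of 1.99 (95% CI 1.10 to 3.59, adjusted p = 0.25), S100a8 had a change of 0.29 and S100a9 -0.06. Wap, Lalba and Csn2 had changes of -0.01, 0.02 and 0.13. At 48 h limma called 0 genes, the smallest adjusted p was 0.203, and 2104 genes had an unadjusted p under 0.05. Of these 2104, 31.2% were higher in E. coli glands, against 50.1% after the arrays were centred on their medians. Leaving out saline replicate 1 of 48 h gave 12 calls, leaving out E. coli replicate 1 gave 57 and leaving out E. coli replicate 2 gave 1.

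As lists, interferon and macrophage genes were higher at 48 h. The 24 type I interferon genes had a median of 0.41 (adjusted p = 1.02e-07, and adjusted p = 0.445 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Rtp4 and Ifih1 had changes of 0.62 and 0.37. The 20 interferon gamma genes had a median of 0.22 (adjusted p = 1.72e-06, and adjusted p = 0.445 with an estimated correlation), with 0 called over all genes and 5 rises adjusted over the list alone. The 20 monocyte and macrophage markers had a median of 0.28 (adjusted p = 1.72e-06, and adjusted p = 0.469 with an estimated correlation), with 0 in both counts, and Ctss and Lyz2 had changes of 0.65 and 0.55. Skeletal muscle markers were lower, with a median of -0.50 (adjusted p = 2.26e-05, and adjusted p = 0.445 with an estimated correlation). Of 13 muscle genes 0 were called over all genes and 9 fell when adjusted over the list alone, and Tnni2 and Eno3, a fast-muscle troponin and a muscle enolase, each had a change of -0.34.

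Complement genes (median 0.23, adjusted p = 0.00896, and adjusted p = 0.489 with an estimated correlation) and leukocyte adhesion genes (median 0.08, adjusted p = 0.0225, adjusted p = 0.0509 with ranks, and adjusted p = 0.373 with an estimated correlation) were higher at 48 h, each with 0 calls over all genes and 2 rises adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.11 (adjusted p = 0.00159, and adjusted p = 0.445 with an estimated correlation), which was 0.02 (adjusted p = 0.850) after a further quantile normalization. The list of ribosomal proteins (median 0.07, adjusted p = 0.0205, and adjusted p = 0.373 with an estimated correlation) and the list of tricarboxylic acid cycle and fatty acid oxidation genes (median 0.06, adjusted p = 0.0220, and adjusted p = 0.582 with an estimated correlation) turned to medians of -0.01 each under that normalization. In these 3 lists 0 members were called, over all genes or adjusted over the list alone. Of the 9 lists called at 48 h, 0 were called with an estimated correlation, 0 by fry and 8 by ranks. The 1 list of the 42 that fry called was not among these 9. The type I interferon median was 0.04 in mouse 1 and 0.68 in mouse 2 at 48 h, the macrophage median 0.06 and 0.46, and the muscle median -0.03 and -0.89. In the same order the medians were 0.015 and 0.46 for interferon gamma, 0.01 and 0.36 for complement, -0.06 and 0.18 for leukocyte adhesion, 0.01 and 0.13 for ribosomal, and 0.015 and 0.11 for tricarboxylic acid cycle genes, and oxidative phosphorylation had 0.04 in mouse 1. Mouse 2 was the mouse with the lowest Actb ratios, which is not a sign of poorer RNA.

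**Figure D2:**
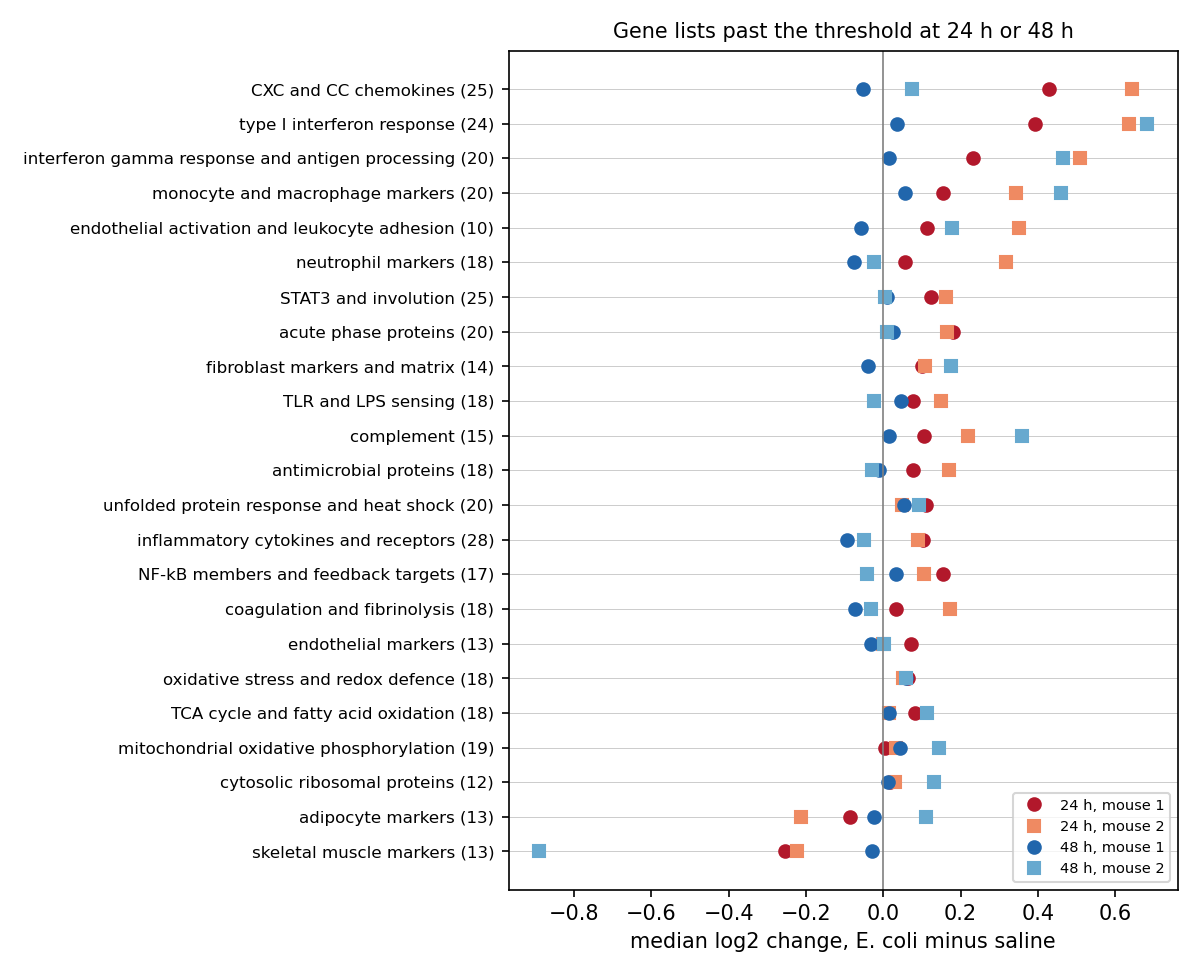
The median log2 change of each gene list, E. coli gland minus saline gland, is plotted on the horizontal axis for each of the 4 mice, with the number of measured genes in brackets. Chemokine medians were 0.43 and 0.64 in the 24 h mice and -0.05 and 0.07 in the 48 h mice. The ribosomal and the tricarboxylic acid cycle lists changed sign at 48 h after a further quantile normalization, with medians of -0.01 each.

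The 2 responses were then compared directly, by testing the difference of the E. coli effects, 48 h minus 24 h. The effect on Cxcl2 was lower at 48 h, by a log2 difference of -2.83 (SE 0.17, adjusted p = 0.000144), and this was the 1 gene that limma called. The next genes by p, Il6 at -1.05 (SE 0.15, adjusted p = 0.188), Plekhs1 at -0.80 (adjusted p = 0.277) and Lysmd3 at 0.76 (adjusted p = 0.285), did not pass. Mtm1 and Pcmt1 had differences of 0.62 and 0.48 (adjusted p = 0.646 and 0.700). Cxcl2 passed in 8 of 8 fits that left out 1 array. The count was 0 without the lowest 33% of genes by mean, which left Cxcl2 out, and 5, 2, 3 and 8 without E. coli replicate 1 of 24 h, E. coli replicate 2 of 24 h, saline replicate 1 of 48 h and E. coli replicate 2 of 48 h.

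Chemokine, cytokine and NF-kB lists had lower E. coli effects at 48 h than at 24 h. The median difference was -0.38 for chemokines (adjusted p = 1.49e-06), with 1 gene lower over all genes and 6 adjusted over the list alone. It was -0.16 for cytokines and receptors (adjusted p = 1.89e-06), with 0 and 5, and -0.19 for NF-kB genes (adjusted p = 7.21e-05), with 0 and 1. These 3 lists were also called with an estimated correlation, but fry did not call the chemokine difference (adjusted p = 0.165). Without both glands of 48 h mouse 1, a fit chosen after seeing the data, the chemokine difference was -0.12 (adjusted p = 0.0439, and adjusted p = 0.365 with an estimated correlation). Neutrophil markers had a median difference of -0.18, and of -0.33 without both glands of 24 h mouse 1, with 3 genes lower when adjusted over the list alone (adjusted p = 8.25e-05, and adjusted p = 0.349 with an estimated correlation). The type I interferon list was not called, so its 24 h and 48 h effects were not shown to differ. In all, 11 of 42 lists were called, 9 lower and 2 higher, and the other 7 had median differences between -0.17 and 0.16.

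Across genes, the log2 changes at 24 h and 48 h, which share no array, had a Pearson r of 0.36 and a Spearman rho of 0.31, where genes are not independent replicates. At an unadjusted p under 0.05, 84 genes were higher at both times against 23.8 expected for independent lists, and 94 were lower against 56.4. Of the 15 genes called at 24 h, 9 had the same sign at 48 h and 2 had an unadjusted p under 0.05 there.

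Saline glands of the 48 h mice were compared with those of the 24 h mice to describe how the control side differed between the 2 times. Heat shock genes were lower at 48 h. Hspa1b and Hspa1a, which encode inducible HSP70 chaperones, fell by 2.05 (SE 0.11, adjusted p = 5.89e-05) and by 2.04 (SE 0.21, adjusted p = 0.0083) on the log2 scale, and Hsph1, an HSP110 chaperone, fell by 1.66 (SE 0.13, adjusted p = 0.00084). Frmd4b, Arg2 and Klf15 fell by 1.35, 1.30 and 1.12 (adjusted p = 0.0227, 0.0110 and 0.0110). The largest rises among called genes were those of Anpep (3.11-fold, 95% CI 1.98 to 4.90, adjusted p = 0.0427), Chil1 (3.10-fold, adjusted p = 0.0126), Cryab (2.37-fold, adjusted p = 0.0357), Hp (2.37-fold, adjusted p = 0.0280), F3, which encodes tissue factor (2.33-fold, adjusted p = 0.0114), and Slc45a3 (2.28-fold, adjusted p = 0.0280).

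In saline glands limma called 79 genes, 48 higher and 31 lower at 48 h, and 1542 had an unadjusted p under 0.05. A grouping of the mice that was not by time called 245 genes over all 8 arrays, so large counts also arise between mice. The list of the unfolded protein response and heat shock was lower (20 genes, median -0.27, adjusted p = 0.000113, and adjusted p = 0.0529 with ranks), with 4 genes lower over all genes and, adjusted over the list alone, 7 lower and 1 higher. Its median was -0.16 (adjusted p = 0.00184) without both glands of 48 h mouse 2, the mouse with the lowest Actb ratios, a fit chosen after seeing the data. The cell cycle list was higher (median 0.12, adjusted p = 0.00958, adjusted p = 0.0517 with ranks, and adjusted p = 0.418 with an estimated correlation), with Top2a called at 0.68 and 7 genes higher when adjusted over the list alone, and it had a median of 0.05 (adjusted p = 0.216) without both glands of 24 h mouse 1 and of 0.20 without those of 24 h mouse 2. Without the mouse block limma called 31 genes, and with only the 4 saline arrays 14. Leaving out saline replicate 1 or 2 of 24 h gave 48 and 4, either E. coli array of 24 h gave 14, and saline replicate 1 or 2 of 48 h gave 5 and 2, while Hspa1b and Hsph1 passed in 8 of 8 fits. Hspa1a and Chil1 passed in 6, Arg2, Klf15 and F3 in 5, Frmd4b and Anpep in 3, Hp and Slc45a3 in 2 and Cryab in 1, and the log2 rise of Anpep ranged from 1.20 to 2.08.

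E. coli glands were compared between the times in the same way. Cxcl2 fell by 2.95 (SE 0.16, adjusted p = 6.71e-05) and Cxcl1 fell by 2.41 (SE 0.29, adjusted p = 0.0144) from 24 h to 48 h. Hspa1a, Hspa1b and Hsph1 fell by 1.95 (adjusted p = 0.0069), 1.63 (adjusted p = 0.000277) and 1.54 (adjusted p = 0.0011), and Sectm1a fell by 0.96 (adjusted p = 0.0421). The largest rises among called genes were those of F3 (2.48-fold, adjusted p = 0.0069), Rb1 (2.41-fold, adjusted p = 0.0486), Efhd1 (2.25-fold, adjusted p = 0.0069), Fcgbp (2.23-fold, adjusted p = 0.0120), Aplnr (2.11-fold, adjusted p = 0.0486) and Kit (1.95-fold, adjusted p = 0.0498). Rb1 and Aplnr passed in 0 of the 8 fits that left out 1 array and Kit in 1, Sectm1a in 2, Cxcl1 in 3, Fcgbp in 4 and Hspa1a in 6, against 7 for F3 and Efhd1 and 8 for Cxcl2, Hspa1b and Hsph1.

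In E. coli glands limma called 51 genes, 29 higher and 22 lower at 48 h, and 1588 had an unadjusted p under 0.05. Chemokines were lower (median -0.45, adjusted p = 1.54e-08), with Cxcl2, Cxcl1 and Cxcl13 called and, adjusted over the list alone, 13 lower and 1 higher, and the median was -0.27 without both glands of 48 h mouse 1. NF-kB genes were lower (median -0.26, adjusted p = 1.96e-05), with Nfkbia called and 3 lower when adjusted over the list alone. The heat shock list was lower (median -0.36, adjusted p = 1.05e-06), with 5 genes lower over all genes and, adjusted over the list alone, 9 lower and 1 higher. Type I interferon genes were lower (median -0.36, adjusted p = 1.96e-05, and adjusted p = 0.340 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone, and their median was -0.12 (adjusted p = 0.765) without both glands of 48 h mouse 1 and -0.66 without those of 48 h mouse 2.

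The number of genes called between the times in E. coli glands fell to 9 without the mouse block, 24 after a further quantile normalization, 11 after median centring, 24 without the lowest 33% of genes, 22 over all probe sets and 4 with only the E. coli arrays. Leaving out saline replicate 1 or 2 of 24 h gave 30, E. coli replicate 1 or 2 of 24 h 10 and 9, either saline array of 48 h 5, and E. coli replicate 1 or 2 of 48 h 15 and 20. Of the genes called in both glands, 22 were higher and 12 lower at 48 h in each, against 0.112 and 0.055 expected for independent lists, where both glands came from the same 4 mice.

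**Figure D3:**
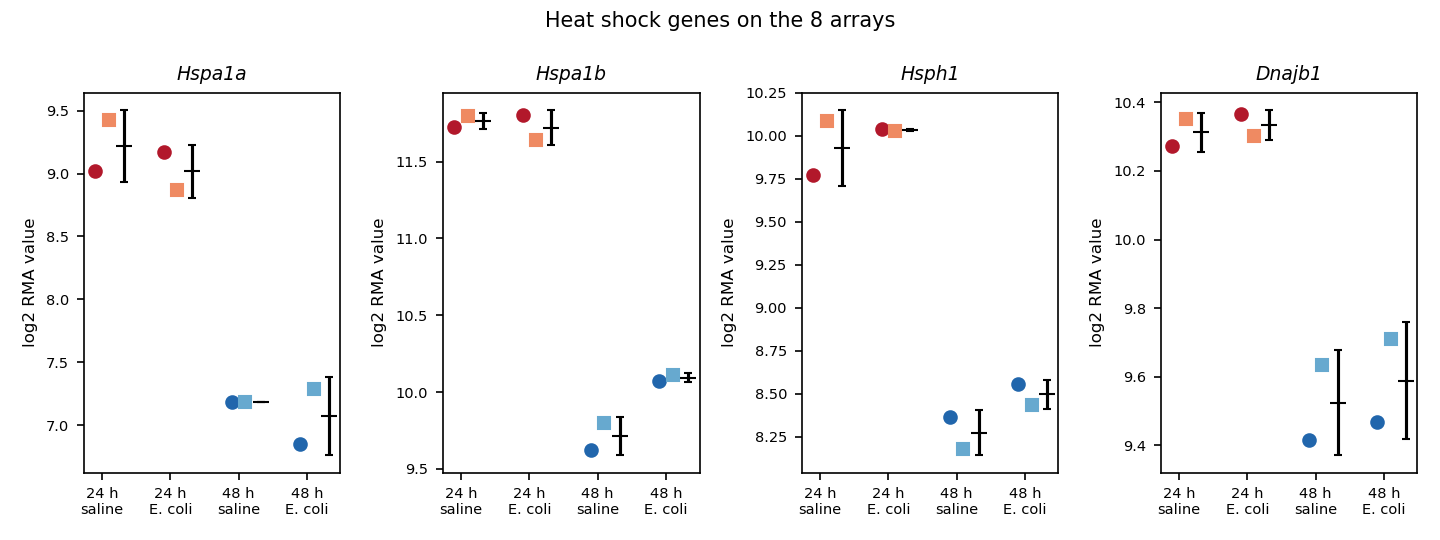
The log2 values of the heat shock genes Hspa1a, Hspa1b, Hsph1 and Dnajb1 are plotted on the vertical axes for the 8 arrays by group, with 1 point per gland (circles for mouse 1, squares for mouse 2) and black bars for the group mean and SD, on axes that do not start at 0. For Hspa1b the lowest value at 24 h was 11.64 and the highest at 48 h was 10.11.

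Averaged over both times, 4 E. coli glands were compared with 4 saline glands. Interferon genes were higher as lists, with a median of 0.43 for type I interferon genes (adjusted p = 4.80e-18) and 0.30 for interferon gamma genes (adjusted p = 2.90e-16). Over all genes 0 members were called, and adjusted over the list alone 17 and 15 rose. Chemokines had a median of 0.32 (adjusted p = 3.51e-07), with 12 higher and 2 lower adjusted over the list alone. Skeletal muscle markers had a median of -0.37 (adjusted p = 4.73e-06, and adjusted p = 0.192 with an estimated correlation), with 10 of 13 lower adjusted over the list alone, and the median was -0.19 without both glands of 48 h mouse 2. For this average limma called 0 genes, with 1885 at an unadjusted p under 0.05, of which 31.1% were higher against 51.0% after median centring. The count was 61 without E. coli replicate 1 of 48 h, 3 with the mouse as a fixed block and 2 with array weights. Of 42 lists 19 were called, 9 of them with an estimated correlation and 0 by fry.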

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

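The tests of a single 24 h mouse, of glands in which the challenge had no effect and of lists without both glands of a mouse were chosen only after the result was seen, and the scaling test was set after the pattern was noticed but before its value was seen. The results below were picked out because the E. coli effect at 48 h differed from that at 24 h in a test of the difference itself.

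Cxcl2 had a lower effect at 48 h, with a log2 difference of -2.83, and the chemokine list had a median difference of -0.38 with the cytokine list at -0.16 and the NF-kB list at -0.19. By fry the chemokine difference did not pass (adjusted p = 0.165). The values argue against a response of 1 mouse alone at 24 h, since the chemokine list stayed lower without either 24 h mouse, with a larger adjusted p of 1.69e-05 (adjusted p = 0.0143 with an estimated correlation), although the gap between the times, 0.354 by medians of single mice, was 0.209 by means, below the 0.354 between the means of the 48 h mice. The chemokine difference was -0.366 after the scaling that moved it most. Array medians already lay between 7.53 and 7.58, so this test had little room to move it. A challenge without effect in the 48 h glands stays open, because mouse 1 had an interferon median of 0.036 and without it the chemokine difference was -0.12 (adjusted p = 0.0439, and adjusted p = 0.365 with an estimated correlation), and because mouse 2, with an interferon median of 0.68, had a chemokine median of 0.074 but a mean of 0.307. A fading of the chemokine response between the days is a candidate explanation, but time cannot be parted from mouse in this design.

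Neutrophil markers had a median difference of -0.18 (adjusted p = 8.25e-05, and adjusted p = 0.349 with an estimated correlation). Acute-phase genes had -0.15 (adjusted p = 0.00322, and adjusted p = 0.106 with an estimated correlation). Their mean log2 values in saline glands were 9.495 and 9.638 at 24 h and 9.676 and 9.802 at 48 h. In E. coli glands the means were 9.81 and 10.107 at 24 h and 9.723 and 9.94 at 48 h. STAT3 and involution genes had -0.11 (adjusted p = 0.0155, adjusted p = 0.0556 with ranks, and adjusted p = 0.106 with an estimated correlation). Here the saline glands were higher at 48 h, with means of 10.392 and 10.379 against 10.215 and 10.027 at 24 h. The E. coli glands were not lower as a group, at 10.418 and 10.394 against 10.422 and 10.257. Antimicrobial genes had -0.12 (adjusted p = 0.0388, adjusted p = 0.0846 with ranks, and adjusted p = 0.0512 with an estimated correlation). Interferon gamma genes had -0.17 (adjusted p = 0.0287, and adjusted p = 0.626 with an estimated correlation). Coagulation genes had -0.09 (adjusted p = 0.0490, adjusted p = 0.0846 with ranks, and adjusted p = 0.443 with an estimated correlation, and adjusted p = 0.148 after a further quantile normalization). Higher at 48 h were the effects on adipocyte markers, at 0.16 (adjusted p = 0.0155, and adjusted p = 0.508 with an estimated correlation), and on milk fat genes, at 0.12 (adjusted p = 0.0156, and adjusted p = 0.535 with an estimated correlation, and adjusted p = 0.262 after a further quantile normalization). Counts of members lower when adjusted over the list alone were 3 for neutrophil markers, 2 for acute-phase genes, 4 for STAT3 and involution genes, 1 for antimicrobial genes and 0 for the other 4 lists, and over all genes each of these lists had 0. Without both glands of 24 h mouse 2, the adjusted p was 0.0957 for antimicrobial, 0.672 for interferon gamma, 0.433 for coagulation, 0.0961 for adipocyte and 0.0972 for milk fat genes. Without those of 48 h mouse 1 it was 0.197, 0.709 and 0.302 for the antimicrobial, interferon gamma and coagulation lists, and without those of 48 h mouse 2 it was 0.0533 for adipocyte and 0.0738 for milk fat genes. Without some mouse the median difference reached -0.33 for neutrophil, -0.25 for acute-phase, -0.175 for STAT3 and involution, and 0.26 for adipocyte genes, and 0.07 for milk fat genes. It ranged from -0.18 to -0.03 for antimicrobial, from -0.34 to -0.01 for interferon gamma and from -0.18 to -0.05 for coagulation genes.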

How the results depend on the processing

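Leaving out both glands of a mouse was chosen only after the results were seen, and all other alternatives were set before. Unless a clause says otherwise the cause was not tested. Stricter criteria lower a count by construction, while leaving out arrays lowered some counts and raised others. Fits to only the 4 arrays compared also left out the mouse block, so they changed more than the number of arrays. Of the 15 genes called at 24 h, 9 lay above the lowest 33% by mean, so that filter lowered the count by leaving the others out. At 24 h, 15 genes were called; the count was 1 with no replicate block, 33 with the mouse as a fixed block, 9 without the lowest 33% of genes, 0 with only the 4 arrays compared, 5 at 2-fold or more and 1 at an adjusted p under 0.01, and it ranged from 1 to 80 when 1 array was left out. It was 9 and 2 without both glands of 24 h mouse 1 or 2, and 38 without either 48 h mouse. At 48 h the count was 0 in the other alternatives, ranged from 0 to 57 when 1 array was left out, and was 28 and 1 without both glands of 48 h mouse 1 or 2. For the difference of effects, with 1 gene called, the count was 0 without the lowest 33% of genes, which left Cxcl2 out, 2 with trend and robust settings, 1 to 8 when 1 array was left out, and 5, 2 and 3 without both glands of 24 h mouse 1, 24 h mouse 2 and 48 h mouse 1.

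In saline glands 79 genes differed between the times, against 31 with no replicate block, 14 with only the 4 arrays compared, 24 at 2-fold or more and 3 at an adjusted p under 0.01. The range was 2 to 66 when 1 array was left out, and 76, 4, 12 and 5 genes were called without both glands of 24 h mouse 1, 24 h mouse 2, 48 h mouse 1 and 48 h mouse 2. In E. coli glands 51 genes differed, against 9 with no replicate block, 24 after quantile normalization, 11 after median centring, 24 without the lowest 33% of genes, 22 over all probe sets, 4 with only the 4 arrays compared, 10 at 2-fold or more and 6 at an adjusted p under 0.01. The range was 5 to 30 when 1 array was left out, and 57, 9, 17 and 3 genes were called without both glands of the same mice. A fixed block could not be fitted for time, because each mouse has 1 time. Over both times 0 genes were called, against 3 with the fixed replicate block, 2 with array weights, 0 to 61 when 1 array was left out and 39 without both glands of 48 h mouse 1.

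Of 42 lists, an estimated correlation called 13 at 24 h in place of 20, 0 at 48 h in place of 9, 3 for the difference in place of 11, 1 in saline glands in place of 8, 4 in E. coli glands in place of 15 and 9 over both times in place of 19. In the same order fry called 3, 1, 3, 1, 6 and 0, and its 1 call at 48 h was not among the 9 lists called there. In saline glands ranks called 2 and no replicate block called 5. Without both glands of 48 h mouse 2, 0 lists were called at 48 h, without those of 24 h mouse 2 the difference gave 7 lists, and without those of 48 h mouse 1 saline glands gave 15. The replicate block changed the number of called lists by less than 1.5 times in the other comparisons. The direction relative to other genes, which camera tests, turned for muscle genes at 48 h without 48 h mouse 2 (adjusted p = 0.784, and 1.25e-18 without 48 h mouse 1), for the difference in interferon gamma genes without 48 h mouse 1 (adjusted p = 0.709, and 3.71e-07 without 48 h mouse 2), and in E. coli glands over time for cholesterol genes without 48 h mouse 2 (adjusted p = 0.853, and 1.15e-05 without 48 h mouse 1) and adipocyte genes without 24 h mouse 2 (adjusted p = 0.628, and 8.78e-06 without 24 h mouse 1). Of their own medians, those of muscle, interferon gamma and cholesterol genes kept their sign, at -0.03, -0.03 and -0.01, and the adipocyte median turned, to -0.015. The median of leukocyte adhesion genes at 48 h turned to -0.06 (adjusted p = 0.581) without 48 h mouse 2. The median of 12 of 20 called lists at 24 h, 9 of 9 at 48 h, 9 of 11 for the difference, 8 of 8 in saline glands, 13 of 15 in E. coli glands and 13 of 19 over both times moved by over 1.5 times or turned without some mouse. Array number and the floor and ceiling of the signal limit all of these.

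With an array left out, the correlation of paired glands was 0.595 to 0.600 without a 48 h array and 0.385 to 0.387 without a 24 h array, against 0.464 with all arrays. The correlation across genes between the effects at 24 h and 48 h was 0.373 without the lowest 33% of genes, against 0.362.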

Other observations

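The second count of other splits below, the test of 1 mouse alone and the values of lists without both glands of a mouse or in single mice were chosen only after the result was seen, and the other tests of muscle and heat shock were set after these patterns were noticed but before the values they measure were seen. The limit of the second muscle list was set before, but its reading as open was settled after its value was seen.

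Further gene groups differed between the times in E. coli glands. Luminal epithelial genes were higher at 48 h (14 genes, median 0.14, adjusted p = 0.00194, and adjusted p = 0.152 with an estimated correlation), with Krt18, a luminal keratin, called over all genes and 2 called when adjusted over the list alone. Tricarboxylic acid cycle and fatty acid oxidation genes were higher (median 0.17, adjusted p = 0.00199, and adjusted p = 0.340 with an estimated correlation), with Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation, called over all genes and 1 adjusted over the list alone. B cell and plasma cell markers were lower (11 genes, median -0.36, adjusted p = 0.00116, and adjusted p = 0.258 with an estimated correlation), with 0 called in both counts. In saline glands, STAT3 and involution genes were higher (median 0.10, adjusted p = 0.00958, adjusted p = 0.0529 with ranks, and adjusted p = 0.116 with an estimated correlation), with Osmr, a receptor chain for oncostatin M, called over all genes and 5 adjusted over the list alone. Krt18, Cpt1a and Osmr were chosen after their values were seen. Without both glands of 48 h mouse 1 the adjusted p was 0.109 for luminal and 0.171 for B cell genes, without those of 24 h mouse 1 it was 0.228 for B cell genes, and without those of 24 h mouse 2 it was 0.434 for the tricarboxylic acid cycle list, with a median of 0.08. The B cell median was -0.12 without 24 h mouse 1 and -0.22 without 48 h mouse 1, the luminal median was 0.27 without 48 h mouse 2, and the STAT3 and involution median in saline glands ranged from 0.06 to 0.23 without a mouse.

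Glucocorticoid target genes, a list of 15 measured genes written after the results were seen, had a median of -0.28 from 24 h to 48 h in saline glands (adjusted p = 0.00402, over 24 tests of added lists) and -0.15 in E. coli glands (adjusted p = 0.0156). Adjusted over the list alone, 5 were lower and 1 higher in saline glands, and 6 lower and 1 higher in E. coli glands. Among probe sets without a gene name, 2 were called between times in saline glands, at -1.55 and 2.52, and 1 in E. coli glands, at 0.81.

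Skeletal muscle genes were lower in E. coli glands by a median of -0.37 over both times (-0.19 without both glands of 48 h mouse 2). The camera test gave an adjusted p of 4.73e-06, and of 0.192 with an estimated correlation. Medians were -0.26 and -0.22 in the 24 h mice and -0.03 and -0.89 in mouse 1 and mouse 2 of 48 h. The mean log2 value was 6.75, while 0 of the 13 are in another list and 1 lies above the median of all genes in saline glands. Drift shared by dim probe sets was smaller than the fall of the muscle list. The medians of 10000 lists matched on mean value centred on -0.06, and the lowest was -0.185. Of the muscle list and these lists, 0.01% had a median as low, the smallest share that number can give. The share was also 0.01% without any 1 mouse, although in 48 h mouse 1 alone it was 74.8%. Matched genes were drawn independently, so the share takes no account of genes that move together. Less muscle taken with the right gland stays open: in a second muscle list of 20 genes, written before the test, the lowest median within a mouse was -0.199, which lies above the bound of -0.2 that would have counted against this explanation by less than its spread of 0.082. Its 4 medians kept the order of the first list, and the lowest was again that of mouse 2 at 48 h. That median did not reach the lower bound also asked for in favour of this explanation, and missed it by more than its spread. The design ties E. coli to the right side, so dissection and infection cannot be told apart for these genes, and Tnni2 and Eno3, the brightest of the list, had means of 8.90 and 7.55.

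Heat shock genes were lower at 48 h than at 24 h in both glands, and no biological explanation was tested beyond the ones given here. In saline glands 4 of 4 called genes passed after the scaling that kept fewest. In E. coli glands the heat shock list had medians of -0.395 after a further quantile normalization and -0.352 after median centring. Array medians already lay between 7.53 and 7.58, so this test had little room to move the genes and does not exclude array scaling. The values argue against 1 mouse alone, since the heat shock list stayed lower in both glands without any 1 mouse. The largest adjusted p was 0.00184, reached in saline glands without 48 h mouse 2, the mouse with the lowest Actb ratios. The median there was -0.16 against -0.27 with all mice. By ranks, though, the list did not pass in saline glands (adjusted p = 0.0529). A second list of 16 genes was lower in both glands, as a wider heat shock response would give, with a larger camera p of 9.13e-07. With an estimated correlation, though, its adjusted p was 0.0514 in saline and 0.0618 in E. coli glands. Not all of its genes were lower. Adjusted over the list alone, 9 were lower and 2 higher in saline glands, and 11 lower and 1 higher in E. coli glands. Over all genes 2 were lower and 1 higher in saline glands, and 0 were called in E. coli glands. Another clock time of sampling may contribute, as 2 clock genes, Nr1d1 and Hlf, passed in both glands when adjusted over the list alone, short of the 3 asked for, so the data do not settle it. Because time is tied to mouse and any handling or processing day, stress before sampling and a change with time cannot be told apart.

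Over both times, 35 of 35 splits of the 8 arrays into 4 and 4 called at least as many genes as the real split, which called 0, and the highest other was 341. A real count of 0 is reached by any split, so this count decides nothing on chance. Of the 3 splits that kept the glands of each mouse together, the one by time called 341, another 245 and the last 3, with 691 at an unadjusted p under 0.05. The 341 and 245 point to a structure of the samples, which the last split did not show to the same extent. Because the 245 came from a grouping of mice that is not by time, large counts between mice can arise without a difference in time. The genes called between 24 h and 48 h can therefore not be credited to time alone. At an unadjusted p under 0.05 the real split gave 1885 genes, 5 of 35 splits gave as many, and the highest other gave 2817, so chance cannot be excluded. Of the 8 splits that part all 4 pairs of glands, the real one gave the most, with 722 as the next, but 8 splits are too few for a share under 0.05. The other splits keep at least 1 pair of glands together and so hold differences between mice.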
